A study of Caenorhabditis elegans with 4 samples.

How the data were processed

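Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites of strain OP203 at the L4 larval stage. The strain carries an unc-119 mutation and an integrated transgene, wgIs203, that expresses the nuclear hormone receptor NHR-76 fused to GFP together with an unc-119 rescue. Per the labels' protocols, synchronised worms were grown at 20 °C on bacteria, crosslinked with 2% formaldehyde, sonicated and incubated with a goat antibody against GFP, and part of each lysate was kept as input DNA. The series holds 4 samples, 2 ChIP samples and 2 input samples, which were grouped by their titles. The free-text descriptions carry the antibody details on the input samples and the words "input DNA" on the ChIP samples, so they were not used for grouping.

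The deposited files are 3 peak lists, one per ChIP replicate and one named as combined. Each line gives a chromosome, a start, an end and a q-value. Per the file headers the coordinates are in genome build WormBase WS180, and per the caller named in each line the authors called the peaks with PeakSeq. The q-value deposited in the score column equalled the one in the attribute column in 3635 of 3635 combined lines, 1562 of 1562 replicate 1 lines and 3676 of 3676 replicate 2 lines. The aligner, the version of the caller, the q-value cut-off, the use of the inputs and the way the combined list was made are not given in the sources used here. The lists hold no read counts or signal, so the sequencing depth of each library is unknown, and a longer list can come from a deeper library, a better enrichment or another threshold. Input read data were not analysed here. No label states whether the 2 ChIP replicates came from separate cultures.

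Peaks were ranked by q-value, then by chromosome and start. The share of peaks in one list that overlapped another by at least 1 bp was compared with 1000 random placements of the second list, each peak keeping its width and its chromosome (permutation test, one-sided, smallest possible p 0.001). Because the files give no chromosome lengths, peaks were placed between the first and the last peak of any list on each chromosome. This span also took the place of the length in densities, in an exact binomial test of each chromosome's share, which was added after the data were seen, and in the test of the central one of 3 equal segments of each chromosome (permutation test, two-sided, smallest possible p 0.002). Rank agreement was Spearman's rho of the q-values across overlapping peaks, each replicate 1 peak being paired with its overlapping replicate 2 peak of smallest q. It is a description across peaks, which are not independent replicates, and has no p-value. Intervals for shares are 95% Wilson intervals and cover counting error only. The p-values called adjusted were adjusted by the Benjamini-Hochberg method within each family, and all others are unadjusted.

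The rule for naming peaks was fixed before the data were examined: the 10 combined peaks of smallest q that overlapped a peak in both replicates. It applied because no gene annotation of build WS180 was used here. The planned assignments to genes, gene groups, genomic features and sequence words, and the values at the nhr-76 and unc-119 loci, were therefore not analysed here. The gene table at hand belongs to another assembly, WBcel235, and only the chromosome it lists for nhr-76 was used, in the closing section. Alternatives were a reciprocal overlap of 50%, peak centres within 100 bp, the better-scoring 50% of each list, lists of equal length, each replicate list alone, the combined peaks held by both replicates, and, added after the data were seen, lists without peaks under 50 bp, the rank agreement in the better-scoring 50% of replicate 1, and the 50% reciprocal and 100 bp centre rules for the support of the strongest and weakest deciles.

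The overlap test was tested on simulated data with the widths and spans of the replicate 1 and replicate 2 lists (1562 and 3676 peaks). Of 10 pairs of unrelated simulated lists, 0 had a p under 0.05, and all 10 pairs with 500 planted shared peaks did. The unrelated lists were made by the same even placement as the test, so this check does not cover lists with clustered peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.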

Results

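To map the genomic binding sites of NHR-76, a member of the nuclear hormone receptor family of ligand-regulated transcription factors, the GFP-tagged protein was immunoprecipitated from L4 hermaphrodites and the bound DNA was sequenced. There were 2 ChIP replicates, each with a matching input. The replicate 1 list held 1562 peaks, the replicate 2 list 3676 and the combined list 3635. Peaks were narrow, with a median width of 334.5 bp in replicate 1, 297 bp in replicate 2 and 296 bp in the combined list. They covered 655.1 kb in replicate 1, 1408 kb in replicate 2 and 1393 kb in the combined list, which was 1.40% of the span between the outermost peaks. The weakest peak kept by the authors had a q-value of 0.000239 in replicate 1 and 0.000387 in replicate 2. Peaks under 50 bp wide made up 2.37% of replicate 1 and 7.78% of replicate 2.

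The first comparison asked which sites were found in both replicates. Nearly all replicate 1 sites recurred in replicate 2. Of 1562 replicate 1 peaks, 1508 overlapped a replicate 2 peak, or 96.5% (95% CI 95.5 to 97.3), against 2.98% for randomly placed peaks (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The reverse share was lower, with 1469 of 3676 replicate 2 peaks (40.0%, 95% CI 38.4 to 41.6) overlapping replicate 1, against 1.26% at random (p = 0.001, one-sided permutation test). When both lists were cut to their 1562 strongest peaks, the shares were 79.5% of replicate 1 and 77.0% of replicate 2. The 2 lists may not be independent, because the replicate 2 list was in large part identical to the combined list, as described further on.

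Support from the other replicate depended on peak strength. In the strongest decile of replicate 2, 365 of 368 peaks (99.2%, 95% CI 97.6 to 99.7) overlapped replicate 1. The share was 53.3% in the fourth decile, where q-values lay between 6.16e-08 and 7.32e-07, and 2.18% (95% CI 1.11 to 4.24) in the weakest decile. In replicate 1, by contrast, the share overlapping replicate 2 was 100% in each of the strongest 3 deciles and was still 92.3% in the weakest. The strongest replicate 2 peak with no replicate 1 counterpart was on chromosome V at 726129 to 728488, 2360 bp wide with a q-value of 2.64e-21. The strongest replicate 1 peak missing from replicate 2 was on chromosome III at 10763407 to 10763517, ranked 492, with a q-value of 2.09e-07. The 54 replicate 1 peaks without a counterpart had a median width of 85 bp, compared with 341 bp for the others.

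**Figure D1:**
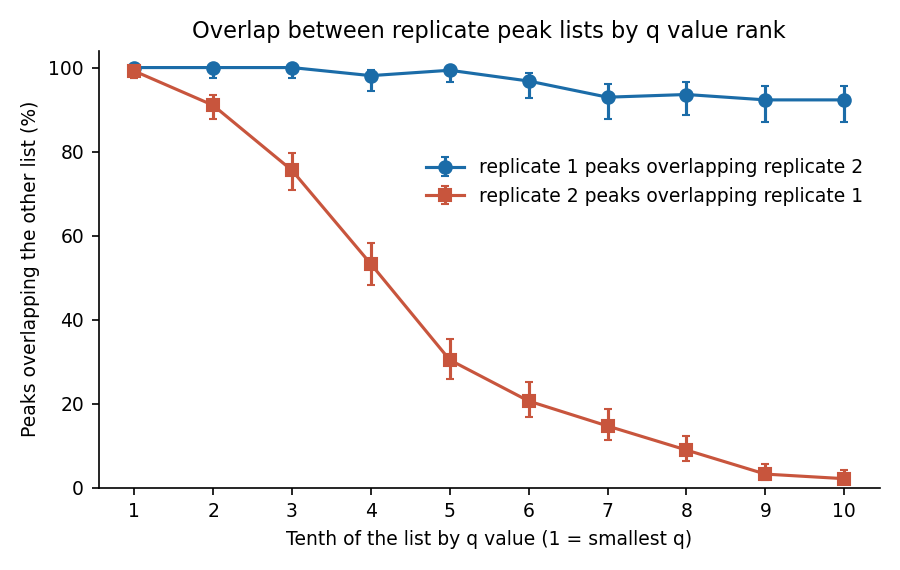
Share of peaks overlapping the other replicate's list by at least 1 bp (vertical axis, percent) in each decile of a list ordered by q-value (horizontal axis), with bars for 95% Wilson intervals. Replicate 1 peaks (circles) stay at or above 92.3%, while replicate 2 peaks (squares) go from 99.2% to 2.18%.

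Sites shared by the replicates were ordered alike by strength. Across the 1508 replicate 1 peaks with a replicate 2 counterpart, Spearman's rho of the q-values was 0.79. Of 1429 peaks that overlapped one to one, 1393 (97.5%) had the smaller q-value in replicate 2 and 1279 (89.5%) were wider there. The median log10 q-value of these sites was -5.23 in replicate 1 and -8.73 in replicate 2. Their median width was 337 bp in replicate 1 and 424 bp in replicate 2, and the median distance between paired centres was 21 bp. Of the 50 strongest replicate 1 peaks, 42 overlapped one of the 50 strongest of replicate 2.

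**Figure D2:**
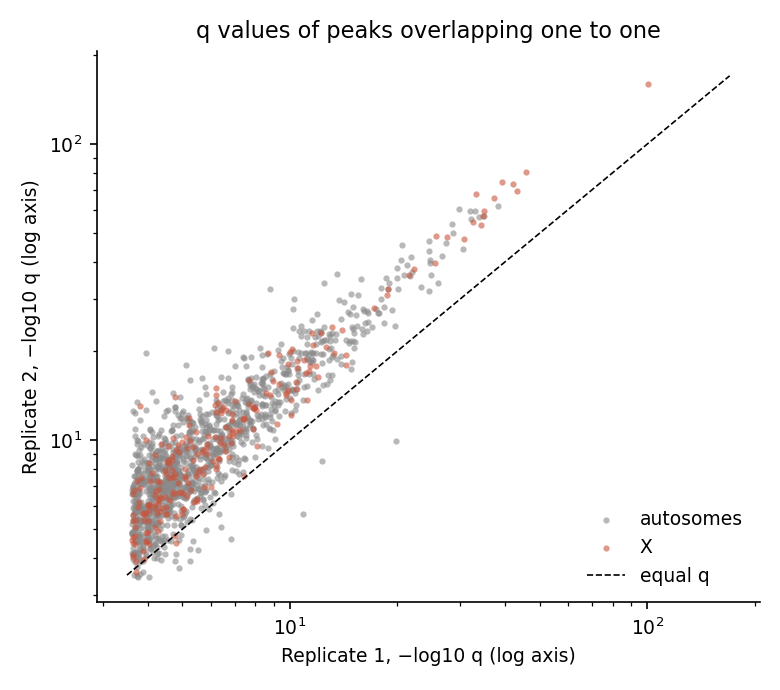
Strength of each peak that overlapped one to one, as −log10 of the authors' q-value in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with peaks on X in red, peaks on autosomes in grey and a dashed line at equal q. Of the 1429 points, 1393 lie above the line.

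The strongest single site was on chromosome X at 16929252 to 16931864 (WS180). It ranked first in each list, with a q-value of 2.72e-101 in replicate 1 and 3.22e-160 in replicate 2. Of the 10 strongest combined peaks found in both replicates, 4 were on X and 3 on chromosome I. The other X sites lay at 14525328 to 14526380, 11093647 to 11094598 and 2996364 to 2997494, and ranked 2, 5 and 4 in replicate 1. Each of these 4 X sites was covered by a single peak in replicate 1 as in replicate 2. The chromosome I sites lay at 7078986 to 7083497, 8866376 to 8869423 and 7656333 to 7659490, and ranked 9, 49 and 51 in replicate 1. The remaining sites were on V at 6220785 to 6225768, on II at 10541896 to 10545483 and on III at 832775 to 836501. They ranked 19, 6 and 23 in replicate 1. The 6 autosomal sites were between 3048 and 4984 bp wide in the combined list, and each was covered by 2 or 3 separate peaks in replicate 1. Their replicate 1 ranks and q-values are those of the peak of smallest q, which covers only part of the site. The q-value on X at 14525328 was 1.40e-46 in replicate 1 and 6.81e-81 in replicate 2. That of the widest of the 10, on V, was 1.07e-32 in replicate 1, for the stronger of 2 peaks, 3191 bp wide. It was 2.32e-86 in replicate 2, for a single peak of 4984 bp, so the 2 values are not for the same stretch. With a single list per replicate, these values have no error of their own.

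The widest enriched region of the genome was on chromosome IV, between 621845 and 652335. In the combined and replicate 2 lists it consisted of a peak of 10550 bp and one of 18986 bp, separated by 955 bp, which together covered 96.9% of the 30.5 kb. The widest peak outside this region was 5722 bp in both of these lists, on chromosome V at 18715698 to 18721419. In replicate 1 the same region on IV also held the widest peak of the list, of 9480 bp, and a second of 2748 bp, covering 40.1% of it. The q-value of the 10550 bp peak was 8.54e-48 and that of the 18986 bp peak 1.16e-19, which ranked 31 and 195 in the combined list. The strain carries additional copies of nhr-76 sequence in its transgene, and input read density over this region was not analysed here.

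Peaks were not spread evenly over chromosomes. Chromosome III carried 725 of the 3635 combined peaks, or 19.9% (95% CI 18.7 to 21.3), on 13.8% of the span, a density of 52.9 peaks per Mb. The other autosomes had between 32.0 and 37.3 peaks per Mb, and X had fewer than any of them in that list. In replicate 1 the sparsest was chromosome I, with 11.2 peaks per Mb compared with 13.8 on X (exact binomial test for I, adjusted p = 2.03e-06). The excess on III was found in each replicate list (exact binomial test against the span, adjusted p = 3.25e-11 in replicate 1 and 1.03e-23 in replicate 2). X held 14.9% of combined peaks (95% CI 13.8 to 16.1) on 17.6% of the span (exact binomial test, adjusted p = 5.25e-05). This call was lost in replicate 1, where the X share was 15.4% (adjusted p = 0.0518, same exact test), and among combined peaks held by both replicates, at 15.9% (adjusted p = 0.173, same exact test). Chromosome V held 18.3% of combined peaks, 0.876 times its share of the span (adjusted p = 0.000197, same exact test), but in replicate 1 its share of 20.4% had an adjusted p of 0.576 in that exact test. Peaks on X were wider, with a median of 369 bp compared with 286 bp on autosomes in the combined list, and 429 bp compared with 323 bp in replicate 1. Neighbouring peaks were treated as independent in the binomial test, although peaks were clustered, so its p-values are too small. The random placements of the overlap and central-segment tests, which set each peak down separately, and Fisher's exact tests share this limit.

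Along the autosomes, peaks were concentrated in the centre. When each span was divided into 3 segments of equal length, the central segments of the autosomes held 41.0% of combined peaks (95% CI 39.3 to 42.8), against 33.4% for random placement (two-sided permutation test, p = 0.002, the smallest possible). The share lay between 39.6% and 42.9% on each of the 5 autosomes, with adjusted p-values of at most 0.008 in that test. Chromosome X had the opposite pattern, with 26.9% of its peaks in the central segment (95% CI 23.4 to 30.8, adjusted p = 0.0024 in the permutation test). The difference between autosomes and X was present in both replicate lists, at 41.2% and 27.8% in replicate 1 (Fisher's exact test, two-sided, p = 7.62e-05) and 40.6% and 28.6% in replicate 2 (p = 6.56e-08). The call on X was lost in replicate 1 alone (27.8%, p = 0.09, permutation test) and among combined peaks held by both replicates (27.5%, p = 0.072, permutation test). The central-segment test was planned because autosome centres hold more genes in this species. Neither its random placement nor the binomial test of chromosome shares allowed for gene density. The central concentration and the excess on III are therefore not shown to be particular to NHR-76.

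**Figure D3:**
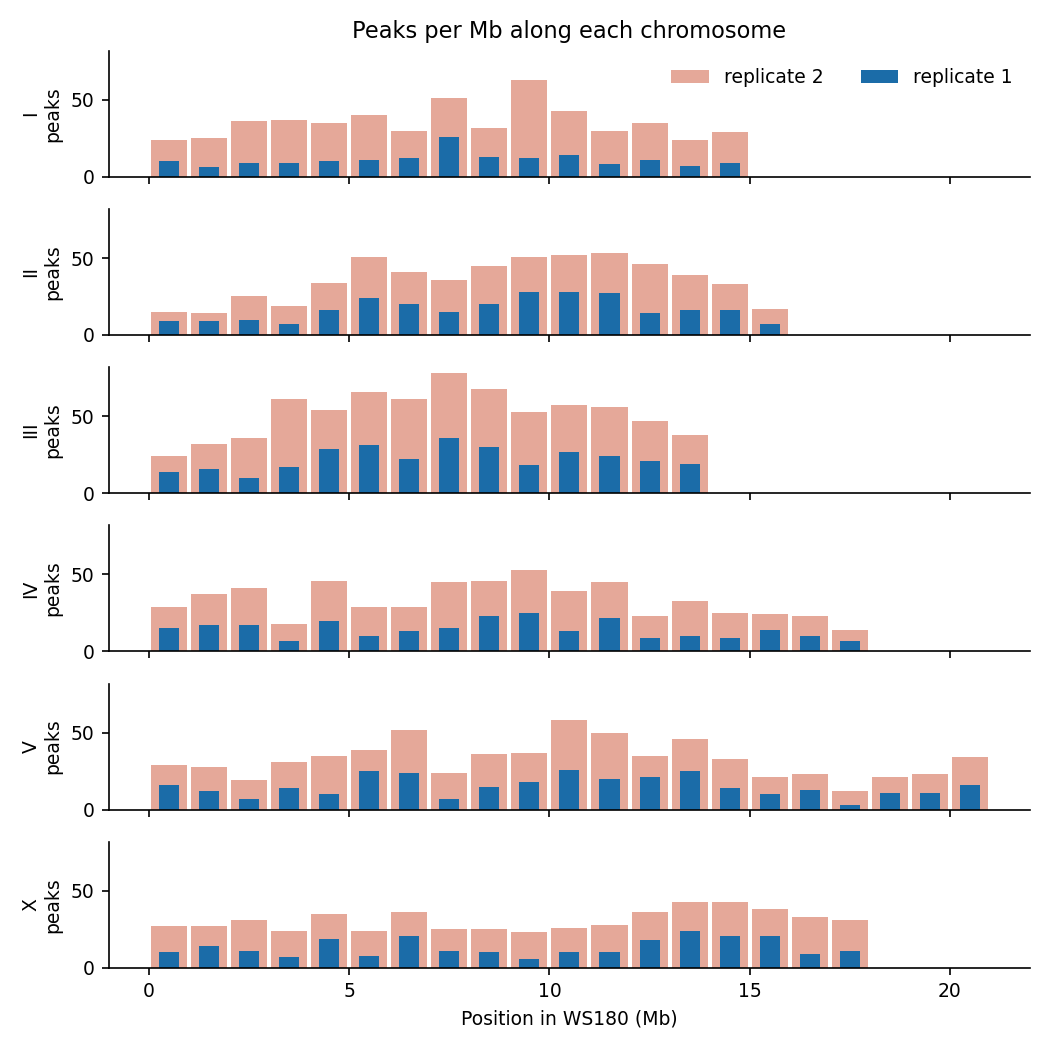
Number of peaks (vertical axis) in each stretch of 1 Mb along the 6 chromosomes (horizontal axis, WS180 position in Mb), for replicate 2 (wide pale bars) and replicate 1 (narrow dark bars). Chromosome III is the most densely covered, and the autosomes are fuller in their central segments.

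The combined list was compared with each replicate to learn how it relates to them. Of its 3635 peaks, 3585 (98.6%, 95% CI 98.2 to 99.0) overlapped replicate 2 and 1469 (40.4%, 95% CI 38.8 to 42.0) overlapped replicate 1, against 2.82% and 1.26% at random (one-sided permutation tests, p = 0.001 each). Only 1468 combined peaks overlapped both replicates, 2117 overlapped replicate 2 alone, 1 overlapped replicate 1 alone and 49 overlapped neither. In 2621 combined peaks (72.1%) the start, the end and the q-value were all identical to those of a replicate 2 peak, including the first-ranked site on X. No combined peak was identical to a replicate 1 peak in this way (0 of 3635). The identical peaks fell in blocks: when chromosomes were divided into 102 stretches of 1 Mb, 70 held identical peaks alone and 32 held at most 6.67% identical peaks. The combined list therefore added almost no sites to the replicate 2 list, and agreement between these 2 lists is not a replicate comparison.

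**Figure D4:**
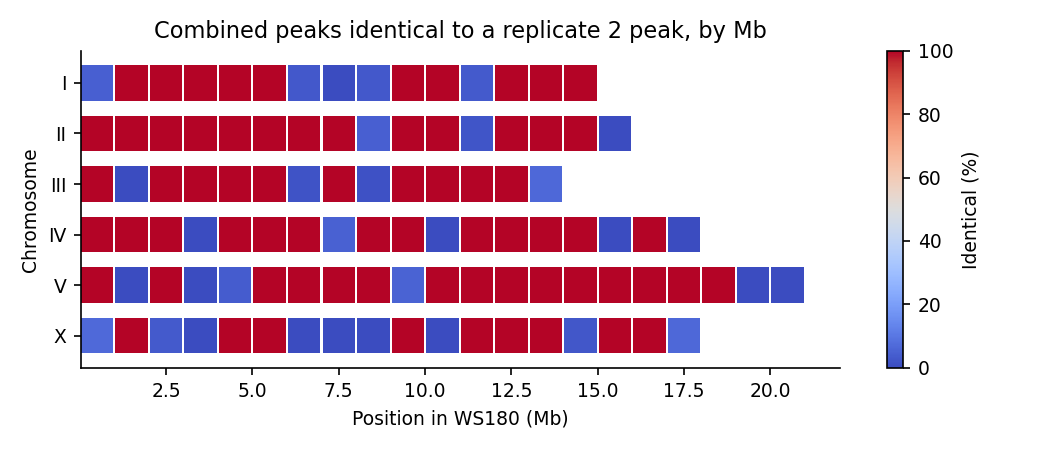
Share of combined peaks with the same start, end and q-value as a replicate 2 peak (colour, percent) in each stretch of 1 Mb (horizontal axis, WS180 position in Mb) of the 6 chromosomes (vertical axis). Of the 102 stretches, 70 are at 100% and 32 at or below 6.67%.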

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

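The 20 alternative overlap values between lists (5 settings for each of 4 shares) all kept their direction and stayed past the threshold. Those for combined peaks are no separate check, because 72.1% of combined peaks were identical to a replicate 2 peak. The size of an overlap depended on list length: with lists of equal length the share of replicate 2 peaks overlapping replicate 1 was 77.0% and that of combined peaks 77.0%. Spearman's rho was 0.82 among one-to-one pairs and 0.83 in the better-scoring 50% of replicate 1, a setting added after the data were seen. Of the strongest decile of combined peaks, 85.2% overlapped replicate 1 under a reciprocal overlap of 50% and 72.3% with centres within 100 bp, both also added later; the cause was not tested. The low share of X peaks in the central segment was 27.5% (p = 0.072, permutation test) among combined peaks held by both replicates. In the replicate 1 list it was 27.8% and missed the threshold (p = 0.09, permutation test) on fewer peaks. In the replicate 2 list it was 28.6%, but that list is in large part the combined list and may hold the reads of both replicates. The share of peaks on X stayed below that of the span, but missed the threshold of the exact binomial test among combined peaks held by both replicates (15.9%, adjusted p = 0.173). It also missed it in the replicate 1 list (15.4%, adjusted p = 0.0518, same exact test). In the replicate 2 list, with the same limit as above, the share was 15.1%. The other central-segment shares kept their calls, and the peak numbers stayed within 1.5 times, under each alternative run. Alternatives for genes, features and words were not run, nor was a second score column, since each list has a single one. No paired analysis was possible because only the ChIP replicates have peak lists. Depth, which the lists do not give, limits any reading of the different list lengths.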

Other observations

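Tests in this part were chosen after the result was seen, except the width-matched comparison of X, the widths of neighbouring peaks on chromosome IV, the share of pairs with the smaller q-value in replicate 2 and the comparison of edges at other thresholds, whose outcomes had been predicted beforehand. Peaks lay closer together than under random placement: 24.1% of combined peaks had another peak within 1000 bp, against 9.82% for random placement (permutation test, one-sided, p = 0.001, the smallest possible), and in replicate 1 the shares were 18.4% and 4.50% (p = 0.001, permutation test). Some neighbours may be pieces of a single site, as at the strongest autosomal sites in replicate 1. The placement also ignored the central concentration of peaks, so clustering of distinct sites is not shown. Outside chromosome IV, the window of 50 kb with the most peak-covered sequence was on V between 6200001 and 6250000, where 13 combined peaks covered 12298 bp and 11 replicate 1 peaks covered 8591 bp. On chromosome I, 28.6% of combined peaks (95% CI 24.9 to 32.6) overlapped replicate 1, compared with 42.5% on the other chromosomes (Fisher's exact test, two-sided, adjusted p = 7.01e-09). The odds ratio was 0.54, and 0.38 within deciles of q-value rank. Of the 1429 peaks paired one to one, 36 had the larger q-value in replicate 2, and 8 had the same start and end in both replicates. The largest such increase, as a ratio of q-values, was on III at 10224449 to 10225341, which is also one of those 8, with a q-value of 1.34e-20 in replicate 1 and 1.13e-10 in replicate 2.

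The combined list repeated replicate 2 in blocks, whereas a list called on the pooled reads of 2 libraries should differ from the list of one of them at nearly every peak, which the 72.1% of peaks with identical start, end and q argue against. The span fell into 102 stretches of 1 Mb: 70 held identical peaks alone and the other 32 held at most 6.67% identical peaks. With mixed meaning over 10% and under 90% identical, 0 stretches were mixed. When identity was reassigned at random 1000 times, 96 to 102 stretches were mixed. In all 32 changed stretches the paired peaks moved one way, being all wider in replicate 2 in 23 and all narrower in 9, by a median of 10 bp, so a candidate explanation is that a single set of reads was called on both occasions, with a threshold set separately for each stretch. Whether that set is replicate 2 alone or both replicates stays open. Of 1429 peaks paired between replicates 1 and 2, 109 had starts that coincided to the base. The mean was 13.1 pairs at each offset from 1 to 10 bp, with the 2 directions counted as separate offsets. Shared reads would give such an excess. Edges fixed by the sequence remain an undecided alternative. The prediction made beforehand was that starts would coincide at least as often at other thresholds as between replicates 1 and 2. It was met, with 13.7% between the combined and replicate 2 lists at other thresholds, compared with 7.63% between replicates 1 and 2. This decides nothing where those lists may share their reads. The smaller q-value in replicate 2 at 97.5% of the replicate pairs would also come from a deeper replicate 2, and 36 of 1429 pairs went the other way.

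The widest peaks, on chromosome IV between 621845 and 652335, may reflect the tagged transgene or a broad binding region. A loose threshold in that stretch of 1 Mb is argued against by its other 27 combined peaks, whose median width was 290 bp, compared with 296 bp in the whole list. Extra copies of the nhr-76 insert would raise the density of reads over the whole insert in every library of this strain, inputs included. How far they would lower the q-values depends on how the inputs were used in peak calling, which is not given. The region held the widest peak of each list. Peaks covered 40.1% of it in replicate 1, compared with 96.9% in replicate 2. Replicate 1 peaks also covered less sequence in total, 655.1 kb compared with 1408 kb in replicate 2. The contrast is therefore not particular to this region and decides nothing here. Since the region was picked for its width, which a broad bound region would also give, the widest peaks do not decide between that and transgene copies. The WBcel235 gene table lists nhr-76 on chromosome IV, but so it does 16.4% of protein-coding genes, and coordinates of that assembly were not set against WS180, so transgene copies and a broad region bound by NHR-76 cannot be told apart here.

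Chromosome X was over-represented among the strongest peaks and not in the rest. It held 17 of the 50 strongest combined peaks (34.0%, 95% CI 22.4 to 47.8) and 14.6% of the others (odds ratio 3.00, Fisher's exact test, adjusted p = 0.00427 over 5 cut-offs). It also held 17 of the 50 strongest in replicate 1 (adjusted p = 0.00235, Fisher's exact test). The combined and replicate 1 lists may share reads, so the second result may not be a separate check. For the 100 strongest the adjusted p was 0.104 in the combined list and 0.145 in replicate 1 (Fisher's exact test). For the 250 strongest the lists differed, with 0.137 in the combined list and 0.036 in replicate 1 (same test). Width as the source stays open: against 150 other peaks matched on width the odds ratio was 1.83 (p = 0.094, Fisher's exact test), and the X peaks among the 50 were narrower than the autosomal ones in the combined list (difference of medians -700 bp, permutation p = 0.0402), with no such difference detected in replicate 1 (-25 bp, permutation p = 0.891). A hypothesis for follow-up is that these are sites where the dosage compensation complex, which acts on X in hermaphrodites, is loaded; no list of such sites in WS180 was used here, so this and binding by NHR-76 itself cannot be told apart.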
